A study of Mus musculus with 17 samples.

How the data were processed

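RNA was measured in cells sorted by flow cytometry from the small bowel of mice that lack the homeobox genes Dlx1 and Dlx2 (Dlx1/2-/-, here mutant) and of wild-type mice (Dlx1/2+/+). The sorted cells are enteric neural crest-derived cells, the precursors, neurons and glia of the nervous system of the bowel. At birth (P0) the cells carried Wnt1-Cre and the R26R-TdTomato reporter, on a CF1 x C57BL/6J x CBA/J background, with 4 wild-type and 5 mutant libraries. At embryonic day 14.5 (E14.5) they carried the EDNRB-L10A-EGFP reporter, on a CF1 x C57BL/6J background, with 4 wild-type and 4 mutant libraries. Groups were taken from the labels. The labels do not say that each library is a separate animal, so p-values measure the spread between these libraries.

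Per the labels' protocols, dispase and collagenase freed the cells, RNA was extracted after sorting, and libraries were made with a stranded total RNA kit for small inputs. The submitters' processing notes name STAR, limma and the genome builds mm10 and GRCm38, with no role or version. The authors deposited 1 table per age of whole-number counts of sense-strand reads per gene. Antisense partners are thus counted apart, but overlapping genes on one strand and near-identical copies may share reads. The totals were nearly equal within each table, 4463830 to 4469731 counts at P0 (a spread of 0.132%) and 6949217 to 6956149 at E14.5 (a spread of 0.0998%). Sequenced libraries seldom come out that close, so the authors appear to have brought them to a common number of reads. That step and the original depths are not given in the sources used here. A separate deposited list per age named 1 gene, mt-Rnr2, with very high counts, and this gene is still in the tables. Gene coordinates below are those of GENCODE M21 on GRCm38. Its identifiers matched 25548 of 25568 genes in the P0 table and 22768 of 22786 in the E14.5 table.

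From the deposited counts, each age was fitted alone with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, quasi-likelihood test, Benjamini-Hochberg adjusted p threshold of 0.05). The tables were not merged, because age, reporter, strain and processing all differ between them. Standard errors of log2 fold changes are the fold divided by the square root of the F statistic. CPM values are edgeR's, on TMM-scaled totals of the tested genes, with a prior count of 2 for means of log2 CPM, and SDs are over libraries. CPM given for single libraries that stood apart are on the plain library totals. For 27 gene lists fixed before the data were examined, limma 3.58.1 gave camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, adjusted over the lists. Members were also adjusted over the list alone. A gene passed, rose or fell over all genes by edgeR, and a list was called by camera with the preset correlation, unless another tool is named. Lists with under 5 tested genes, the Dlx genes and the sex genes were not put to a list test. The change at each age was compared by the difference of the 2 log2 folds over its standard error, with a normal approximation. Intervals on ratios of counts are exact at a confidence level of 95%, the floor for a count of 0 is 3 counts over the group, and both cover counting error only.

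The genes named were set by a rule before the data were examined. It takes the Dlx genes, Vip, Nos1, Chat, Penk, Gal, Tac1, Cartpt and Npy whatever they show (Vip is known to be a focus of the study, so it is no independent choice). It takes up to 12 rises and 12 falls per age among changed genes with a mean of at least 20 counts and no overlap between groups, leaving out predicted genes, pseudogenes and sex genes. From each list it takes up to 4 members that passed and 2 further examples. It also takes genes that changed at both ages or differed between ages, changed genes within 5 Mb of Dlx1 and Dlx2, and the 10 smallest p where fewer than 5 genes changed.

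The tests were run on simulated counts with known changes. For the P0 comparison edgeR recovered 71% of 2-fold and 97% of 4-fold changes among 13886 genes, and 6.67% of its calls were false. For the E14.5 comparison it recovered 57.6% and 89% among 13195 genes, with 3.95% false. DESeq2 had 11.8% and 9.41% false calls in the same simulations. In these, about 100 genes changed at each fold, and genes varied independently. Where fewer genes change, the cut on p is stricter, so recovery in the data may be lower. The test of the difference between ages recovered 90 of 100 genes with opposite changes and called 14 unchanged ones among 12648.

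Alternatives were DESeq2 1.42.0, limma-voom, other scalings, filters and thresholds, a surrogate variable (sva 3.50.0), replicate number or title date as a block, a Y-linked covariate and leaving out each library. Covariates for the neuron minus glia score and for the immediate early score, the Y-linked covariate for the lists, and DESeq2 for the difference between ages were added after seeing the data. No 2 libraries of a group agreed within sampling noise, with a chi-square per gene of 7.06 to 17.1 at P0 and 8.15 to 17.8 at E14.5. Sample titles hold dates whose meaning is not given. At P0, 1 wild-type and 2 mutant libraries share a date, and at E14.5 1 library of each genotype does. A fold with the date as a block thus rests on these libraries alone. The sex of the animals is not given in the labels. By Xist and Y-linked counts, Y-linked reads were present in 2 of 4 wild-type and 3 of 5 mutant libraries at P0. This leaves aside P0 mutant library 2, which was high in Xist and had only 2 Y-linked counts. At E14.5 Y-linked reads were present in 3 of 4 wild-type and 1 of 4 mutant libraries.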

Results

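Sorted enteric neural crest-derived cells of the small bowel were compared between Dlx1/2 mutant and wild-type mice at P0 (5 and 4 libraries) and at E14.5 (4 and 4 libraries). Each P0 library held 4463830 to 4469731 counts, with 18492 to 20285 genes detected. Each E14.5 library held 6949217 to 6956149 counts, with 15973 to 18552 genes detected. The median standard error of a log2 fold change was 0.21 at both ages.

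The targeted genes were low in every mutant library. Dlx1 (ENSMUSG00000041911, chromosome 2, 71528113 to 71533981, plus strand) and Dlx2 (ENSMUSG00000023391, chromosome 2, 71543408 to 71546754, minus strand) encode homeobox transcription factors. At P0, Dlx1 had 326 ± 21.3 counts in wild-type libraries (SD, n = 4) and 25.6 ± 5.41 in mutants (SD, n = 5), which left 7.85% of the wild-type level with an exact 95% interval of 6.49% to 9.41%. At E14.5, Dlx1 had 916 ± 48.4 counts in wild-type libraries (SD, n = 4) and 69.3 ± 21.7 in mutants (SD, n = 4), or 7.56% with an interval of 6.67% to 8.55%. Dlx2 fell further. It had 212 to 379 counts in P0 wild-type libraries and 0 or 1 in P0 mutants, a total of 3 against 1161, which left 0.207% with an interval of 0.0426% to 0.606%. At E14.5 it had 525 to 771 counts in wild-type libraries and 0 to 6 in mutants, or 0.418% with an interval of 0.209% to 0.750%. Dlx1as, the RNA antisense to Dlx1, had 0 counts in all mutant libraries and a total of 23 at P0 and 19 at E14.5 in wild-type libraries. Against a floor of 3 counts over the group it was 9.58-fold and 6.33-fold lower. The exact 95% interval is looser and reached up to 13.9% of the wild-type level at P0 and 21.4% at E14.5. Wild-type library 1 held 13 of the 19 counts at E14.5, and without it the fold at that floor was 2.67. Counts per gene do not show which exons the remaining Dlx1 reads come from, and the extent of the deletion is not given in the sources used here. Dlx3 and Dlx5, the other Dlx genes tested, did not pass edgeR's quasi-likelihood test at either age. Dlx5 differed by 0.29 ± 0.45 at P0 and by -0.13 ± 0.28 at E14.5 (log2 fold ± SE), and Dlx3 by -0.57 ± 0.37 and 0.25 ± 0.91. Leaving out each library, Dlx5 ran from 0.04 to 0.50 at P0 and from -0.30 to 0.07 at E14.5, and Dlx3 from -0.96 to -0.35 and from -0.48 to 0.87.

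**Figure D1:**
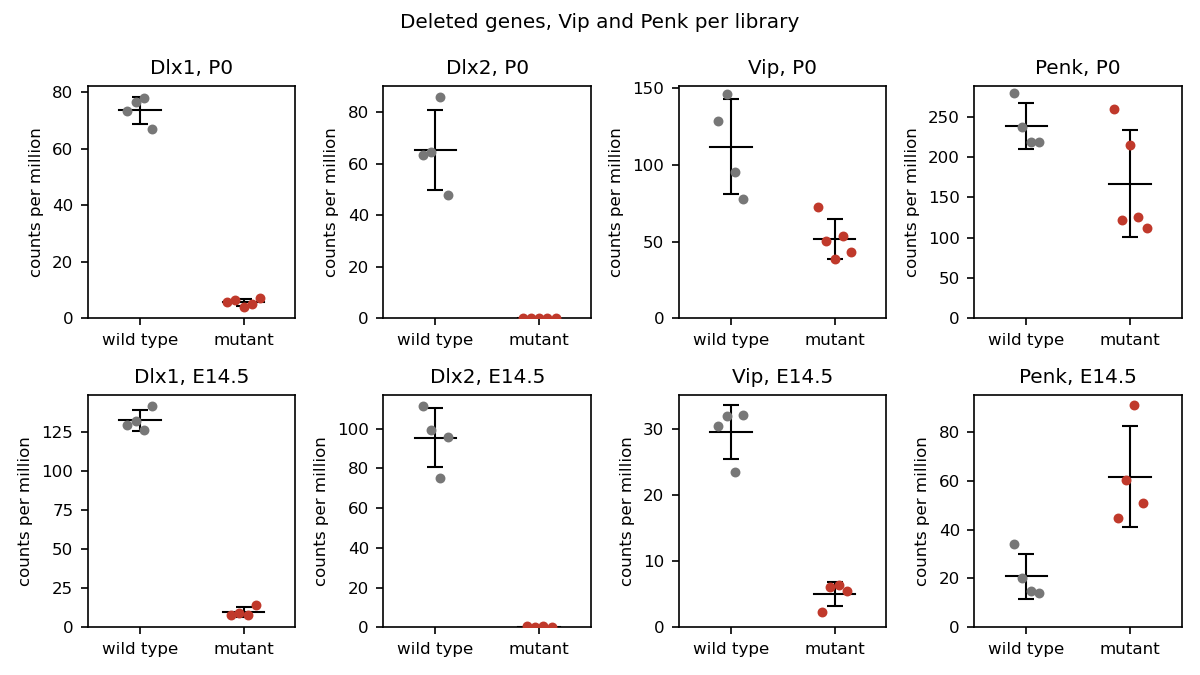
CPM of Dlx1, Dlx2, Vip and Penk in each library (points), by genotype and age, with the mean (line) and SD (bars) on linear axes that start at 0. Vip was lower in every mutant than in every wild-type library at both ages, while Penk was higher in every mutant library at E14.5 and overlapped between genotypes at P0.

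The P0 comparison asks which genes differ in the newborn bowel without Dlx1 and Dlx2. Beyond the deleted genes no gene passed, while the inhibitory neuron peptides Vip and Cartpt were among the lowest p-values with lower means in mutants. Vip, vasoactive intestinal peptide, a transmitter of inhibitory enteric neurons (chromosome 10, 5639218 to 5647617), had 112 ± 31.0 CPM in wild-type libraries (SD, n = 4) and 51.9 ± 13.2 in mutants (SD, n = 5), a log2 fold of -1.11 ± 0.20 with an adjusted p of 0.0967 by edgeR's quasi-likelihood test. Cartpt, which encodes a neuropeptide precursor, had a log2 fold of -1.27 ± 0.22 with an adjusted p of 0.0919. The other genes among the 10 smallest p were Slc15a2, a peptide transporter (3.33 ± 0.54), Lrrn3 (-0.90 ± 0.16), Rassf1 (1.05 ± 0.19), Scgn, a calcium-binding protein (-1.36 ± 0.26), and the immediate early genes Fos (1.13 ± 0.21) and Junb (1.26 ± 0.24). None of these passed in edgeR, while DESeq2 called all of them. Leaving out 1 library, edgeR called Slc15a2 without wild-type library 1 (where its fold was 4.23), mutant library 3 or mutant library 4, Vip and Cartpt without wild-type library 4, and Rassf1, Fos and Junb without mutant library 3. With the title date as a block the fold of Vip was -0.68 ± 0.30.

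Of 14140 genes tested at P0, 2 changed, Dlx1 (log2 fold -3.67 ± 0.19) and Dlx2 (-8.65 ± 0.37), both lower. For Dlx2, with so few mutant counts, the standard error may be too small. DESeq2 gave one of 0.86 at P0 and of 0.47 at E14.5. At an unadjusted p under 0.05 there were 1039 genes (7.35%), and 313 genes (2.21%) did not overlap between the groups, where chance gives 1.59%. DESeq2 called 45 genes, 29 higher and 16 lower, and limma-voom 2. Without wild-type library 2 the count was 11, without wild-type library 4 it was 4, and without mutant library 3 it was 15.

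Among gene lists at P0, neuronal groups lay lower in mutants, and the glial, fibroblast, cell cycle and immediate early groups lay higher. Of 18 markers of VIP and nitrergic neurons, 16 were lower, with a median log2 fold of -0.40. Over all genes 0 of them passed in edgeR and 3 in DESeq2, and adjusted over the list alone 8 fell, among them Cartpt, Vip, Ebf1, a transcription factor (-0.96 ± 0.24), and Nos1, neuronal nitric oxide synthase (-0.70 ± 0.22, but 0.0068 with the title date as a block), and 1 rose, Col5a2, a collagen (0.56 ± 0.13). Leaving out 1 library, 3 to 9 fell, with 3 without wild-type library 2, 4 without wild-type library 1 or mutant library 5 and 5 without mutant library 2, and Nos1 kept its call in 6 of 9 such fits. Camera with the preset correlation called the list lower, with an adjusted p = 0.176 with an estimated correlation. Of 24 pan-neuronal genes 22 were lower, with a median of -0.39. Over all genes 0 passed in edgeR and 0 in DESeq2, and adjusted over the list alone 12 fell, among them Prph, peripherin (-0.54 ± 0.15), Stmn3 (-0.57 ± 0.16), Eno2, neuron-specific enolase (-0.87 ± 0.27), and Gng3 (-0.65 ± 0.20, but 0.089 with the date block). Those calls depended on single libraries: 0 fell without wild-type library 1 or 2 or mutant library 2 or 5, and 1 without mutant library 3. The fold of Eno2 was -0.57 without wild-type library 2. The pan-neuronal list was called lower, with an adjusted p = 0.239 with an estimated correlation.

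Further neuronal lists at P0 were called lower with the preset correlation, with 0 members passing adjusted over the list alone unless stated or where 1 library was left out. These were synaptic vesicle genes (27 of 32 lower; adjusted p = 0.287 with an estimated correlation), voltage-gated ion channels (36 of 42 lower; adjusted p = 0.319 with an estimated correlation) and transmitter receptors (36 of 42 lower; adjusted p = 0.283 with an estimated correlation). Cholinergic and tachykinin neuron genes were lower in 14 of 17 (adjusted p = 0.256 with an estimated correlation), among them Tac1, the substance P precursor (-0.68 ± 0.23), and Slc5a7, the choline transporter (-0.53 ± 0.21), while Chat, choline acetyltransferase, had a log2 fold of 0.06 ± 0.30. Gal, the galanin precursor, had -0.40 ± 0.16 (-0.24 without wild-type library 2) and Npy, neuropeptide Y, -0.07 ± 0.74, and neither passed. Gal, Npy and Chat changed sign with the date block, and Slc5a7 and Npy with the neuron minus glia score as a covariate. Other transmitter genes were lower in 17 of 22 (adjusted p = 0.256 with an estimated correlation). Of 19 genes linked to DLX1 and DLX2 in the forebrain 12 were lower and 1, Vip, fell adjusted over the list alone (adjusted p = 0.280 with an estimated correlation). The mitochondrially encoded genes, a sign of RNA quality or cell state, were lower in 11 of 12, with a median of -0.43 (adjusted p = 0.256 with an estimated correlation). Adjusted over the list alone, 6 transmitter receptors fell without wild-type library 4 or mutant library 1, 3 synaptic vesicle genes without wild-type library 3 or mutant library 1 and 2 without wild-type library 4, 3 cholinergic genes without mutant library 1, 2 other transmitter genes without mutant library 3 or 4, and 9 mitochondrial genes without wild-type library 2 and 5 without mutant library 5. The forebrain list lost camera's call without wild-type library 2 or mutant library 3.

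The immediate early and heat shock genes, which tissue dissociation is known to raise, lay higher in P0 mutants. Of 28, 25 were higher, with a median log2 fold of 0.69. Over all genes 0 passed in edgeR and 7 in DESeq2, and adjusted over the list alone 17 rose, among them Fos, Junb, Jun (0.77 ± 0.15) and Klf2 (1.78 ± 0.36). The list had an adjusted p = 0.0432 with an estimated correlation and 0.0476 by fry, but each of these calls held in 1 of the 9 fits that left out 1 library, that without mutant library 3. Its score per library had an exact two-sided permutation p of 0.0159, but 0.116 adjusted over the 22 scores tested, so the score did not pass. Within the title date that 1 wild-type and 2 mutant libraries share, the mean log2 CPM of the list was 5.49 in the wild-type library and 6.24 in the mutants. Fibroblast genes, markers of another cell type, were higher in 14 of 14, with a median of 0.43, adjusted p = 0.0348 with an estimated correlation and 0.0476 by fry, calls that held in 4 and 1 of the 9 fits. Their score did not pass either (exact permutation p = 0.00794, the smallest these libraries can give, but 0.0873 adjusted). It did not overlap between the genotypes, at 5.74 to 5.84 in wild-type and 6.07 to 6.42 in mutant libraries. Of the members 0 passed either way, but 7 rose over the list alone without mutant library 1, 4 without wild-type library 3, 2 without mutant library 4 and 1 without wild-type library 2. Glial and progenitor genes were higher in 22 of 24 (median 0.24; adjusted p = 0.176 with an estimated correlation), such as Sox10, a transcription factor of enteric progenitors (0.36 ± 0.14) with 0 passing. Cell cycle genes were higher in 33 of 37 (adjusted p = 0.409 with an estimated correlation), and genes of BMP, WNT, Notch and Hedgehog signalling in 24 of 36 (adjusted p = 0.176 with an estimated correlation). Camera's call of both was lost without wild-type library 2, and that of the signalling genes also without mutant library 4. In all, 14 of 22 lists were called at P0 with the preset correlation, 5 higher and 9 lower, and 2 with an estimated correlation.

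**Figure D2:**
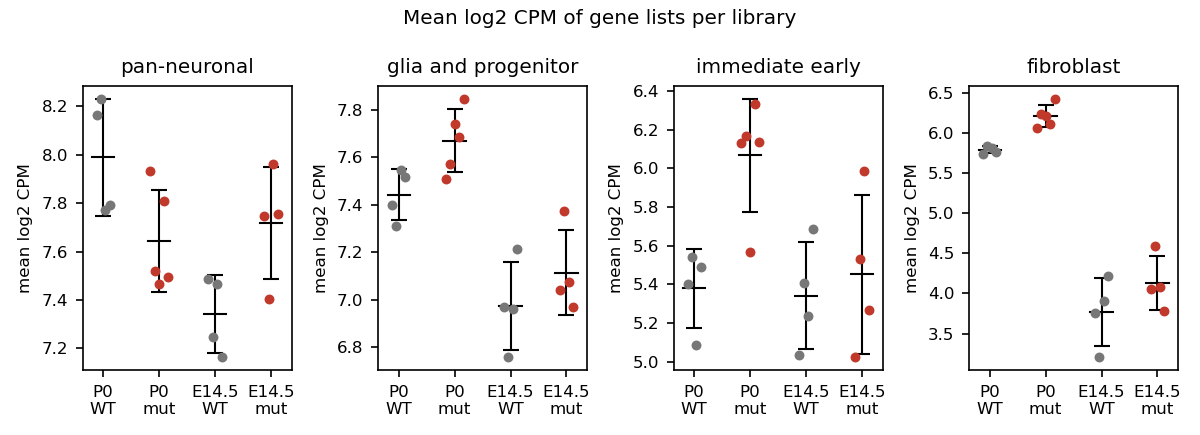
Mean log2 CPM of the tested genes of 4 lists in each library (points), by age and genotype, with the mean (line) and SD (bars); the axes do not start at 0. The immediate early score lay between 5.08 and 5.54 in P0 wild-type libraries and between 5.56 and 6.33 in P0 mutants, while the pan-neuronal score overlapped between genotypes at both ages.

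The E14.5 comparison asks the same of the embryonic bowel. Vip fell from 29.5 ± 4.06 to 5.06 ± 1.84 CPM (SD, n = 4 and 4), a log2 fold of -2.54 ± 0.28 with an adjusted p of 9.67e-05 by edgeR's quasi-likelihood test. Penk, the enkephalin precursor (chromosome 4, 4133531 to 4138819), rose from 20.8 ± 9.21 to 61.6 ± 20.6 CPM, a log2 fold of 1.56 ± 0.26 with an adjusted p of 0.0142. Lifr, the receptor for leukemia inhibitory factor, fell, with a log2 fold of -1.24 ± 0.15. Slc17a6, a vesicular glutamate transporter, was at 0 counts in 3 of 4 wild-type libraries, with 4 counts over the group, and had 154 counts over the mutants, where it rose, a ratio of 38.5 with an exact 95% interval of 14.7 to 143 for counting error alone. Its fitted log2 fold of 5.08 ran from 4.71 to 8.26, the latter without wild-type library 4, when each library was left out, and its call held in 2 of 8 such fits.

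Of 13521 genes tested at E14.5, 23 changed, 8 higher and 15 lower in mutants. Further rises included Lrp1b (1.75 ± 0.31), the matrix protease Mmp2 (1.58 ± 0.28), the collagen Col3a1 (1.00 ± 0.20), the homeobox gene Hoxb6 (0.98 ± 0.18) and Gja1, connexin 43 (0.78 ± 0.14). Besides Dlx1 (-3.74 ± 0.18), Dlx2 (-7.85 ± 0.38, and -8.53 without mutant library 3), Vip and Lifr, the falls included Capn6 (-1.79 ± 0.30), the dynamin Dnm3 (-1.28 ± 0.17), Chodl (-1.20 ± 0.22), Fmn1 (-1.14 ± 0.22), Irs1, an insulin receptor substrate (-0.98 ± 0.19), Col25a1 (-0.93 ± 0.15), Etl4 (-0.79 ± 0.13) and the netrin receptor Unc5c (-0.78 ± 0.15). At an unadjusted p under 0.05 there were 966 genes (7.14%), and 576 genes (4.26%) did not overlap between groups, where chance gives 2.86%. DESeq2 called 80 genes and limma-voom 25. With a Y-linked covariate, the sexes being unequal between the groups, 16 genes were called, 11 of them among the 23, with 10 higher and 6 lower. With the title date as a block 4 genes were called, 2 of them among the 23; the folds were then -2.47 for Vip and 0.57 for Penk, and neither passed. Without wild-type library 3 the count was 9, without wild-type library 4 or mutant library 1 it was 12, and without mutant library 3 it was 7. Dlx1, Dlx2, Vip, Dnm3 and Lifr were among the genes called in all 8 fits that left out 1 library. Penk, lost without wild-type library 3 or mutant library 3, Col25a1 and Capn6 were called in 6, Mmp2 and Gja1 in 4, Lrp1b, Hoxb6, Chodl and Etl4 in 3, Col3a1, Irs1 and Unc5c in 2 and Fmn1 in 1.

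Among inhibitory neuron markers at E14.5, 9 of 15 were lower. Vip passed over all genes. Adjusted over the list alone 3 fell, Vip, Ass1, an arginine-recycling enzyme (-0.52 ± 0.13), and Nos1 (-0.85 ± 0.25). Nos1 was called in 4 of the 8 fits that left out 1 library. With the date block, which sets 1 library against 1, the fold of Nos1 was 0.53. That list was not called by camera or by fry's test of direction, but it was by fry's test for change in either direction (adjusted p = 7.25e-04). The list holds Vip, and this test was not repeated without it. Of the peptides named in advance, Gal had a log2 fold of 0.40 ± 0.20 and Cartpt 0.54 ± 0.28, and neither passed. Chat had 0.35 ± 0.31. Leaving out each library, Cartpt ran from 0.31 to 0.91 and Chat from 0.09 to 0.69. Npy and Tac1 were below the count filter, with 50 and 0 counts over the wild-type and 19 and 6 over the mutant libraries.

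Pan-neuronal genes lay higher in E14.5 mutants. Of 24, 21 were higher, with a median log2 fold of 0.38. Over all genes 0 passed in edgeR and 1, Dcx, in DESeq2, and adjusted over the list alone 10 rose, among them the neurofilament genes Nefl (0.89 ± 0.21) and Nefm (0.90 ± 0.25), Dcx, doublecortin (0.61 ± 0.15), and Rtn1 (0.50 ± 0.14, but 0.32 without mutant library 3). Leaving out 1 library, 3 to 16 rose, with 3 without wild-type library 4 or mutant library 1 or 3, 6 without wild-type library 2 and 16 without mutant library 2, and Nefl and Dcx were called in all 8 such fits. Camera with the preset correlation called the list higher, with an adjusted p = 0.624 with an estimated correlation. Cholinergic and tachykinin neuron genes were higher in 10 of 13 (adjusted p = 0.624 with an estimated correlation), with Penk, Casz1 (0.79 ± 0.18) and Chgb (0.52 ± 0.15) rising adjusted over the list alone and 1, Penk, over all genes. Synaptic vesicle genes (23 of 32 higher; adjusted p = 0.624 with an estimated correlation), ion channels (28 of 38 higher; adjusted p = 0.624 with an estimated correlation) and fibroblast genes (9 of 13 higher; adjusted p = 0.624 with an estimated correlation) were also called higher, and cell cycle genes lower (23 of 37 lower; adjusted p = 0.624 with an estimated correlation). Thus 6 of 19 lists were called, 0 with an estimated correlation and 0 by fry. By fry's test for change in either direction 10 lists were called, against 0 of 22 at P0. That test was not repeated leaving out libraries or over other splits, and some of its lists hold genes that passed over all genes. Without wild-type library 2 or mutant library 4, camera called 3. Synaptic vesicle, ion channel and cell cycle genes lost the call without wild-type library 2 or mutant library 3 or 4, synaptic vesicle genes also without wild-type library 1, and fibroblast genes without wild-type library 2 or mutant library 2.

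Members of other E14.5 lists moved in both directions. Of 16 genes linked to DLX1 and DLX2 in the forebrain 10 were higher, with a median of 0.08; Vip fell over all genes (DESeq2 also called Robo2), and over the list alone Vip fell and Robo2 rose. That list was not called by camera, but it was by fry's test for change in either direction (adjusted p = 2.64e-05). It holds Vip, which passed over all genes, and the test was not repeated without Vip. Of 14 other transmitter genes 8 were higher; Slc17a6 rose over all genes, and adjusted over the list alone Slc17a6 and Chgb rose and Slc18a2, a vesicular monoamine transporter (-0.44), fell, the latter in 4 of the 8 fits that left out 1 library. Among glial and progenitor genes, 1 passed over all genes, and adjusted over the list alone 4 rose, among them Apoe, apolipoprotein E (1.09 ± 0.23), and Ngfr, a neurotrophin receptor (0.44 ± 0.11), and 2 fell, such as Nes, nestin (-0.55 ± 0.12). Among enteric transcription factors, adjusted over the list alone, Ebf3 fell (-0.68 ± 0.14) and Casz1, Hoxb3 (0.34 ± 0.10) and Hoxb5 (0.37 ± 0.11) rose, with 0 over all genes in edgeR and 2, Ebf3 and Casz1, in DESeq2. Hoxb3 and Hoxb5 were each called in 3 of those 8 fits. Among axon guidance genes, 7 rose adjusted over the list alone, such as the semaphorins Sema3d (1.33 ± 0.29) and Sema3e (2.09 ± 0.53) and the receptor Robo2 (0.60 ± 0.14), and Unc5c fell. Without mutant library 3 only 1 of these rose, Sema3d, and without wild-type library 4 the count was 4. Among transmitter receptors, the glutamate receptor genes Grik3 (-0.60 ± 0.12) and Gria3 (-0.84 ± 0.18) fell and the nicotinic receptor gene Chrna4 (1.00 ± 0.22) rose, adjusted over the list alone, with 0 over all genes in edgeR and these 3 in DESeq2.

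Setting the ages side by side asks whether the loss of Dlx1 and Dlx2 shifts the same genes in embryo and newborn. Dlx1 and Dlx2 were lower at both ages, as the genotype sets, and no other gene of the 12926 tested at both passed at both in edgeR. DESeq2 gave 4 genes, adding Vip and Fbln2, the latter named after its values were seen. Across genes, which are not independent replicates, the folds at both ages had a Pearson correlation of -0.0104 and a Spearman correlation of -0.0973, and 45.8% had the same sign. Without Dlx1 and Dlx2 these correlations were -0.0649 and -0.0978. Of the other 21 genes changed at E14.5, 14 had the same sign at P0 (exact binomial p = 0.189), and their folds had a Spearman correlation of 0.458. Of these 21, 9 had an unadjusted p under 0.05 at P0, against 7.35% of all genes tested there. Adjusted over these 21 alone 3 passed at P0, Vip and Chodl, lower at both ages, and Gm37063, higher at P0 but lower at E14.5.

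In 85 genes the change differed between the ages, higher at P0 in 33 and lower in 52. Penk had a log2 fold of 1.56 at E14.5 and -0.51 ± 0.22 at P0, where it did not pass, a difference of -2.08 ± 0.34. Lifr (difference 1.19 ± 0.20) and Col25a1 (1.19 ± 0.22) fell at E14.5 and had -0.05 ± 0.13 and 0.26 ± 0.16 at P0. The predicted gene Gm37063 differed by 4.03 ± 0.68, and Alcam, a cell adhesion molecule, by -1.20 ± 0.23. Alcam passed at neither age in edgeR, while DESeq2 called it lower at P0. Age, reporter, strain and library dates all differ between the tables. DESeq2 gave 28 such genes and limma-voom 97. On simulated counts the test called 14 unchanged genes beside 90 that truly differed, so part of the 85 may be false calls.

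**Figure D3:**
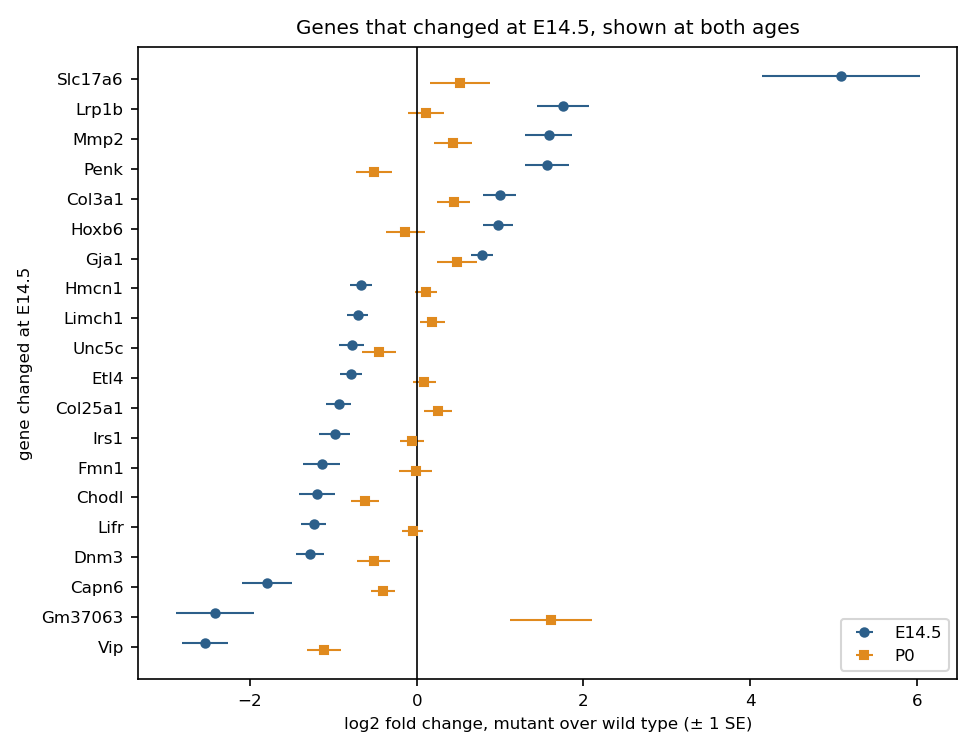
Log2 fold change (mutant over wild type) with 1 standard error at E14.5 (circles) and P0 (squares) for 20 of the 21 genes other than Dlx1 and Dlx2 that changed at E14.5. Vip lay below 0 at both ages (-2.54 and -1.11), and Penk above 0 at E14.5 and below it at P0.

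Near the deleted genes, within 5 Mb on chromosome 2, 59 other genes were tested at each age and 0 were called by edgeR. DESeq2 called 3 of them at E14.5, all higher in mutants and named after their values were seen, Osbpl6 (0.79 ± 0.18 in edgeR), Gpr155 (1.41 ± 0.33) and Rapgef4 (2.06 ± 0.58). At E14.5, 7 had an unadjusted p under 0.05 (11.9%, against 7.11% elsewhere; Fisher's exact two-sided p = 0.195), and at P0 3 did (5.08% against 7.34%; p = 0.800 by the same exact test).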

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

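All tests of explanations in this part were chosen after the results were seen, as was the rule that an exact test of a library score counts only when adjusted over all 22 scores; the splits of the samples were set beforehand, but those of both tables jointly were drawn again after a fault in the first draw was corrected.

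Immediate early genes were higher in the P0 mutants, with a median log2 fold of 0.69, but their score per library did not pass (exact permutation p = 0.0159, adjusted 0.116). Sex of the animals is argued against, since the median was 0.63 with a Y-linked covariate and the lower quartile, 0.37, stayed above 50% of the main median. A shift from neurons to glia stays open: the immediate early score minus the glia score was higher in mutants by 0.46, with an exact two-sided permutation p of 0.0873 (0.190 adjusted). The dates in the titles stay open as well, because the shared date holds 1 wild-type and 2 mutant libraries, which differed by 0.747 where the SD of the wild-type libraries was 0.21. An effect of genotype stays open too, untested against these.

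Vip was lower in the P0 mutants, and lower in 5 of 5 mutant libraries than in any wild-type one. A lower share of neurons may account for part of it: Vip minus the pan-neuronal score differed by -0.75, with an exact two-sided permutation p of 0.00794, the smallest these libraries can give, but 0.0873 adjusted over the scores. With the neuron minus glia score as a covariate the log2 fold was -0.49. With the title date as a block it was -0.68 ± 0.30, from a single wild-type library of the shared date. Both explanations stay open, beside an effect of genotype.

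Of the 35 splits of the E14.5 libraries, 1, the real one, gave as many as its 23 changed genes. The highest other gave 11. That is the lowest share 35 splits can give, not adjusted over the tests of splits. The 23 include Dlx1 and Dlx2, which the genotype fixes. Chance is thus made unlikely for that count but not excluded. The imbalance in sex is argued against as the whole cause, since a median of 94.4% of the fold remained with a Y-linked covariate over the 21 changed genes other than Dlx1 and Dlx2, with a lower quartile of 87.1%. All 21 kept their sign and an unadjusted p under 0.05 in edgeR, but only 9 were still called. Folds were mostly smaller and the median standard error went from 0.185 to 0.193, but the cause of the lost calls was not tested. The dates cannot be told apart from genotype: a median of 83.5% of the fold remained with a date block (quartiles 74.3% and 97.4%), and 0 of the 21 were called at a median standard error of 0.324, in a fit where 1 library of each genotype shares a date.

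At P0 the 2 changed genes are the deleted ones, which the genotype fixes, so the splits say nothing of chance for a response; 10 of 100 gave 2 or more, and the highest other split gave 120. That split set wild-type libraries 2 and 4 and mutant libraries 4 and 5 against the rest, and so high a count points to a structure of the samples. Wild-type library 4 and mutant libraries 4 and 5 share a title date, but the 13 other splits that keep these 3 together gave 0 to 1 genes. Those 4 libraries had the lowest scores of the epithelial list, at 4.22 to 4.60 against 5.14 to 6.36 in the other 5, a difference noticed after the split was seen. With the date as a block 2 genes were called, Dlx1 and Dlx2. For the lists chance could not be excluded: 24 of 100 splits gave at least the 14 lists called at P0 (highest other 17), and 12 of 35 gave at least the 6 at E14.5 (highest other 11).

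A total of 85 genes changed differently at the ages by the test of the difference. As many were given by 2 of 100 joint splits of both tables, the real split and another that gave 536. That share was below the limit set beforehand for naming chance as the explanation. The other grouping still gave far more genes, so chance is not excluded for that count. For the 2 genes changed at both ages, 1 of 100 joint splits gave as many, the real one, and the highest other gave 0, but these are the deleted genes, so the design fixes this outcome and it says nothing of a shared response. The Spearman correlation of the folds at both ages, -0.0973, was matched or exceeded in its distance from 0 by 20 of 100 joint splits, the real one included, so chance could not be excluded. The differences of log2 folds (P0 minus E14.5) with the smallest p were Penk (-2.08), Lifr (1.19), Gm37063 (4.03), Col25a1 (1.19) and Alcam (-1.20).

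Single libraries stood apart from the others of their group in 25 of 412 sets of values (6.07%, where chance gives about 1 in 20). At P0 wild-type library 2 was high in Cacna1c (84.4 CPM) and wild-type library 3 low in Junb (19.7 CPM). Mutant library 3 was low in Btg2 (43.9 CPM) and in the immediate early score (5.56). Mutant library 4 was high in Dlx3 (15.2 CPM) and Hey2 (177 CPM), and mutant library 1 in Ebf1 (16.8 CPM), Syt4 (49.0 CPM) and Unc5d (14.54 CPM). At E14.5 wild-type library 2 was low in Chrna4 (12.2 CPM), in detected genes (15973) and in its scaling factor (0.970). Wild-type library 4 was high in Dlx1 (142 CPM) and Slc17a6 (0.575 CPM, the others at 0), wild-type library 3 high in Hoxa5 (121 CPM) and Isl1 (1.29 CPM), and wild-type library 1 low in Nes (264 CPM) and Robo2 (64.6 CPM). Mutant library 2 was high in Cryab (4.17 CPM) and Gpm6a (9.93 CPM). Mutant library 3 was low in Dlx5 (8.92 CPM) and high in Hoxa5 (166 CPM), Robo2 (158 CPM) and Rtn1 (235 CPM), and mutant library 4 was low in Ngfr (330 CPM).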

How the results depend on the processing

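The covariates for list scores, the Y-linked covariate for the lists, DESeq2 for the difference between ages, and leaving out libraries for calls over a list alone or for lists by fry or with an estimated correlation were chosen after the results were seen. Dlx1 and Dlx2 kept their direction and call in all settings at both ages. The number of changed genes did not keep its size, and the cause was not tested. At P0 it was 2, and 45 with DESeq2, 98 with no low-count filter, 21 with 1 surrogate variable, 13 at an adjusted p under 0.1, 132 with the immediate early score as a covariate and 22 with the replicate block; leaving out each library gave 2 to 15. At E14.5 it was 23, and 80 with DESeq2, 136 with no low-count filter, 50 with 1 surrogate variable, 39 at an adjusted p under 0.1 and 4 with the date block; leaving out each library gave 7 to 31, and the replicate block 16. The lists called were 14 at P0, and 2 with an estimated correlation, 2 with fry, 17 with the replicate block and 13 to 16 leaving out each library. They were 6 at E14.5, and 0 with an estimated correlation, 0 with fry, 6 with the replicate block and 3 to 9 leaving out each library, with 3 without wild-type library 2 or mutant library 4. Genes changed at both ages were 2, and 4 with DESeq2. Genes that differed between ages were 85, and 28 with DESeq2. The correlation between ages was -0.0104, and 0.0112 over genes with a mean of at least 20 counts; without Dlx1 and Dlx2 it was -0.0649 and -0.0719, so that change of sign rests on these genes.

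Same-numbered libraries correlated at 0.095, 0.18, 0.27 and -0.10 at P0, where other pairs ran from -0.33 to 0.22. At E14.5 they correlated at 0.047, -0.16, 0.075 and -0.041, where other pairs ran from -0.11 to 0.20. These values show no pairing by replicate number at E14.5. At P0 the highest of all pairs, wild-type and mutant library 3, was same-numbered but of different title dates. Wild-type and mutant library 4, which share a date, correlated at -0.10. Wild-type library 4 and mutant library 5, of that same date, correlated at 0.22. The replicate block gave 22 changed genes against 2 at P0, so a pairing there is not excluded.

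Some named genes that did not pass over all genes changed sign, and the cause was not tested. The date block rests on the libraries of the shared date alone. The genes that changed sign with it were at P0 Dlx3 (0.63), Nos1 (0.0068), Chat (-0.15), Gal (0.12), Npy (0.47), Gng3 (0.089), Col25a1 (-0.13) and Coro1a (0.030). At E14.5, where it sets 1 library against 1, they were Nos1 (0.53), Chat (-0.076), Slit2 (0.092), Mki67 (0.010) and Hspa1b (-1.31). With the neuron minus glia score at P0 they were Dlx3 (0.26), Nos1 (0.010), Npy (1.68), Etv1 (0.0015), Slc5a7 (0.066) and Mapt (0.12), and at E14.5 Dlx3 (-0.15). With the immediate early score at P0 they were Dlx5 (-0.25), Chat (-0.89) and Btg2 (-0.23), and at E14.5 Dlx5 (0.0037). Mapt is itself part of the neuron score and Btg2 of the immediate early score. Their changes of sign are thus in part built into these covariates. Npy at P0 also changed sign with limma-voom (0.91), the replicate block (0.55), 1 surrogate variable (0.58) and the Y-linked covariate (0.40). Leaving out each library, folds ran from -0.15 to 0.38 for Chat, -0.46 to 1.46 for Npy and -0.11 to 0.022 for Lifr at P0, and from -0.48 to 0.87 for Dlx3 and -0.30 to 0.069 for Dlx5 at E14.5.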

Other observations

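The tests of library scores and of the Hox genes were chosen after the results were seen. The smallest exact permutation p these libraries can give is 0.00794 at P0 and 0.0286 at E14.5. A single score at that p could not pass once adjusted over all 22 scores.

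Markers of other cell types were measured in the sorted cells. At P0, smooth muscle genes were higher in 11 of 15, genes of the interstitial cells of Cajal in 4 of 5, epithelial genes in 11 of 19 and endothelial genes in 5 of 8, and none of these lists was called by camera or fry. Of the immune genes 2 of 4 were higher and Cd68, a macrophage gene (1.29 ± 0.37), rose adjusted over the list alone, though not without mutant library 2, with 0 over all genes in edgeR or DESeq2. Erythroid genes (1 of 2 higher) and mesothelial genes (4 of 4 higher) had 0 passing. Among p53 and cell death genes, Btg2 (1.19 ± 0.26) and Cdkn1a (0.77 ± 0.23) rose adjusted over the list alone, with 0 over all genes in edgeR and 1, Btg2, in DESeq2, and the list was not called by camera or fry. Btg2 is also among the immediate early genes that rose adjusted over their list alone, so its rise here is not a separate result. Cdkn1a was called in 4 of the 9 fits that left out 1 library. Genes of RET and endothelin signalling were higher in 6 of 16, enteric transcription factors in 15 of 36 and axon guidance genes in 24 of 67, with none of these lists called by camera or fry. Opcml (1.14), a cell adhesion gene, rose and Slit3 (-0.59), an axon guidance ligand, fell adjusted over the axon guidance list alone, with 0 over all genes in edgeR and 1, Opcml, in DESeq2. Opcml was called in 7 and Slit3 in 2 of those 9 fits. The median (0.07) and mean (-0.03) of the epithelial list differ in sign, as do the median of the RET list (-0.02) and its test, which points up.

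At E14.5, smooth muscle genes were higher in 8 of 13, genes of the interstitial cells of Cajal in 2 of 4, epithelial genes in 4 of 4, endothelial genes in 1 of 3, immune genes in 2 of 2 and mesothelial genes in 2 of 2, while 0 erythroid genes were tested. Coro1a (0.85 ± 0.34) and Nkain4 (1.42 ± 0.37) rose adjusted over the immune and mesothelial list alone, with 0 over all genes in edgeR and 1, Nkain4, in DESeq2. Coro1a was called in 4 of the 8 fits that left out 1 library, with a fold of 0.55 without mutant library 3. Immediate early genes were higher in 17 of 24, p53 genes in 12 of 17, mitochondrially encoded genes in 7 of 9, RET and endothelin genes in 8 of 14 and BMP, WNT, Notch and Hedgehog genes in 20 of 31. None of these 5 lists or the smooth muscle list was called by camera, and by fry's test for change in either direction 1 was, the BMP, WNT, Notch and Hedgehog list (adjusted p = 0.0369). Sex genes were higher in 4 of 5 at P0 and in 1 of 5 at E14.5.

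Pan-neuronal genes may be shifted in opposite directions at the ages. The score per library differed by -0.34 at P0 (exact two-sided permutation p = 0.0794, adjusted 0.190) and by 0.38 at E14.5 (exact permutation p = 0.0857, adjusted 0.190), so the tests do not decide.

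Hox genes, a group chosen after their values were seen, may be higher in the E14.5 mutants. Of 17 tested, 14 were higher, with a median log2 fold of 0.37, 1 passing over all genes and 7 over the group alone, but 1 without mutant library 3, 3 without wild-type library 4 and 10 without wild-type library 2. The mean score was higher by 0.37, with an exact two-sided permutation p of 0.0286, the smallest possible here, but 0.157 adjusted over the scores, so the test does not decide. At P0, 13 of 17 were higher and 0 passed, or 1 to 2 over the group alone without wild-type library 1 or mutant library 2 or 5.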
